A study of Arabidopsis thaliana with 4 samples.

How the data were processed

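Small RNA libraries of 4 stages of pollen development were analysed, 1 library per stage. Per the labels, plants grew in 16-h days at 21 °C, spores of the first 3 stages were enriched on percoll gradients and mature pollen was isolated from flowering plants. RNA below 200 nt was tailed with poly(A), ligated to a 5' adapter, reverse transcribed and amplified, a gel fraction of 120 bp (with 98 bases of flanking sequence) was recovered, and 2 barcoded samples were sequenced per channel on an Illumina Genome Analyzer II; which stages shared a channel is not given in the labels. The deposited values are whole-number counts per distinct tag, not normalized. The submitters' processing notes name the build TAIR9; the aligner and the steps from reads to tags are not given in the sources used here. In the files, tag lengths run from 18 to 24 nt and 0 tags end in A, so terminal A bases appear to have been removed with the added poly(A), and a tag whose next genomic base is A may be longer than listed. Among single-locus 22-nt tags the next base was A in 56.2% to 71.2%, and among 24-nt tags in 36.7% to 41.3%.

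The mature pollen file lists 204515 tags in 2 runs of tag numbers. Of the 393 tags with at least 100 counts in each of the other libraries, it lists 16.0%, against 99.7% to 100% for each complete library checked the same way. In the complete libraries the composition did not change along 12 consecutive blocks of tag numbers (for example, 24-nt tags made up 12.3% to 12.8% of the tags of each block in the uninucleate microspore), so the listed tags were treated as a random part. The range given for a share in mature pollen is the central 95% of 1000 random parts of the same size of the library it is compared with. The total of mature pollen was estimated at 2618760 counts (2111650 to 3091990 from parts of tricellular pollen, 1727590 to 3369890 from parts of the uninucleate microspore). Intervals of single miRNAs in mature pollen join the tricellular range with counting error in both comparisons. Against the uninucleate microspore they are thus narrower than its own range would give.

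Each distinct tag was matched exactly to TAIR10.1, with Python 3.11.15 and NumPy 2.4.6; all coordinates come from this match and are 1-based. A tag with several loci went to 1 class in the order rRNA, tRNA, snRNA or snoRNA, MIRNA, TAS, protein-coding exon, pseudogene, plastid, mitochondrion, other. The nuclear rRNA class also took the 4000 bp downstream of 5.8S genes and the copies of the 120-nt 5S rRNA. This annotation gives no transposable element superfamilies (24 of 4851 pseudogenes carry a note naming a transposon), so the planned results by superfamily were not run and annotated pseudogenes are reported in their place. Mature miRNAs were 88 sequences written down before the data were examined, less terminal A bases, each found inside an annotated MIRNA gene, in 6 lists by target or age. Genes that share a mature sequence are 1 entry.

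Shares carry Wilson 95% intervals, and the ratio of 2 counts an exact conditional (Clopper-Pearson) 95% interval, computed with SciPy 1.17.1. No p-value is given, since each stage is 1 library. A miRNA counts as changed when it has at least 20 counts over both libraries, a ratio of at least 4-fold and an interval that excludes 1. A list's median is given with its percentile among 10000 random lists of the same size matched on expression in 4 bins, drawn from all annotated mature sequences with at least 20 counts, for lists of at least 3 measured members. The floor for a count of 0 is 3 counts. The rule for named miRNAs, fixed before the data were examined, took the 5 highest and 5 lowest ratios of each adjacent pair of stages and the 10 highest and 10 lowest of the first against the last stage, among those with at least 50 counts over the 4 libraries and an interval that excludes 1, the 10 most abundant, members of a list where it is described, and the 3 largest TAS genes and tRNA isotypes. As mature pollen lists a part of its tags, the rule was applied to tricellular against uninucleate in place of mature against uninucleate, and abundance was averaged over the 3 complete libraries.

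The comparison of counts was tested on simulated data, with Poisson counts drawn from the real means of 350 annotated sequences and 200 of them changed. These counts hold counting error only and no variation between libraries, so the numbers below do not cover false calls from such variation. For bicellular against uninucleate, 16 of 17 measured sequences with a true 8-fold change and 8 of 12 with a true 4-fold change were called in the right direction, and 0 of 38 unchanged ones were called. For tricellular against bicellular these were 11 of 12, 9 of 14 and 0 of 23, and for tricellular against uninucleate 19 of 20, 11 of 24 and 0 of 34.

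Alternatives changed 1 choice at a time: totals without rRNA, tRNA, snRNA and snoRNA tags; DESeq2 1.42.0 size factors and edgeR 4.0.16 TMM over the miRNAs, in R 4.3.3; tags within 2 nt of both ends of the miRNA; minimums of 100 and of 1 count; a 2-fold rule; tags with a count of 1 left out; distinct tags; genome-matching tags; structural RNA left out; 1 mismatch, with bwa 0.7.19; fractional and single-locus assignment; TAS tags of all lengths; and thinning to the shallowest complete library. Chosen after the data were seen were nuclear tags whose next base is not A, totals without mitochondrial tags, all annotated mature sequences, rRNA from annotated genes only, pseudogene tags without an organelle match, TAS1A without its most counted tag of mature pollen, and the comparison of tricellular with uninucleate. The first of these changed more than 1 choice. It also left out structural RNA, MIRNA, TAS, organelle-matching and unmatched tags.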

Results

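Small RNAs were sequenced from male spores of Arabidopsis thaliana (accession Ler-0) at 4 consecutive stages: the uninucleate microspore, bicellular pollen (after the first pollen mitosis), tricellular pollen (after the generative cell has divided into the sperm cells) and mature pollen. Each stage was 1 library, so no difference between stages has a replicate check, and every interval below covers counting error only. The deposited files listed distinct tags of 18 to 24 nt with their counts, 3439985 counts in the uninucleate microspore, 2480584 in bicellular pollen and 2374615 in tricellular pollen. The mature pollen file held 428521 counts in 2 runs of tag numbers, of 3266 and 201249 tags, which is 16.4% of its last tag number. Mature pollen tags with other numbers were not analysed here, so mature pollen was described by shares, whose ranges cover listing a part of the tags, and a sequence missing from that list was not read as absent. Between 73.8% and 79.6% of each library's counts matched the reference genome exactly. A count of 0 allowed up to 0.872 on the counts-per-million scale (RPM) in the uninucleate microspore, 1.21 in bicellular pollen, 1.26 in tricellular pollen and 7.00 in the listed part of mature pollen.

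A pair of miRNAs dominated the counts of exact mature sequences, the only tags used for the ranks and shares of this paragraph. miR158a-3p (MIR158a, AT3G10745, chromosome 3, 3366349 to 3366368) was the most abundant, at 10476 RPM in the uninucleate microspore, 5891 in bicellular pollen and 2347 in tricellular pollen. miR859 (MIR859, AT1G60072, chromosome 1, 22149735 to 22149755) followed at 5988, 2531 and 1344 RPM. Together they held 72.9%, 67.8% and 58.1% of the exact mature miRNA counts of these 3 libraries. Length variants were left out of these ranks and shares. In the uninucleate microspore, tags within 2 nt of both ends of miR172c/d-3p, named after its values were seen, held 25106 counts. Those of miR172a/b-3p held 23451, and these length variants were not assigned to either entry. Exact miR172c/d-3p held 1637. The other members of the 10 most abundant exact sequences were miR403-3p, which targets AGO2, miR158b, miR161.2, which targets pentatricopeptide repeat genes, miR159a, which targets GAMYB-like transcription factors, miR396a-5p, which targets growth-regulating factors, miR162a/b-3p, which targets DCL1, miR156a-f-5p, which targets SPL transcription factors, and miR775. Of the 88 mature miRNAs looked for, 59 were counted in the uninucleate microspore, 59 in bicellular pollen and 58 in tricellular pollen, and 20 had no count in any library.

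**Figure D1:**
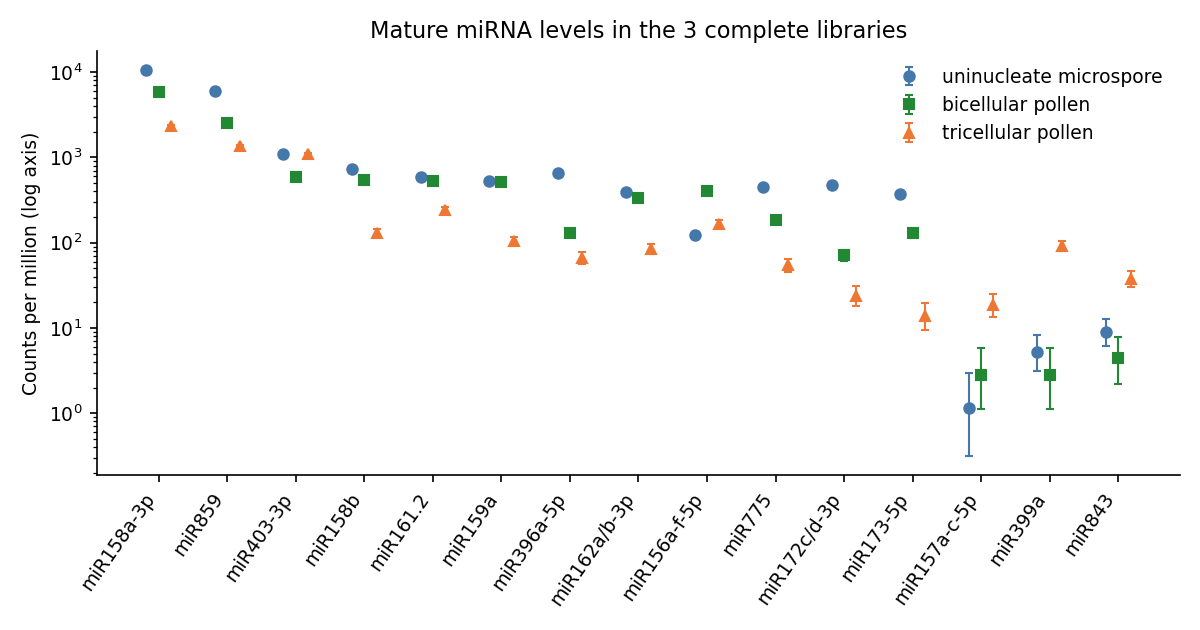
Levels of 15 mature miRNAs, the 10 most abundant followed by 5 others named in the text, in RPM on a log axis; symbols are the 3 complete libraries and bars are exact 95% Poisson intervals of the counts. miR158a-3p fell from 10476 to 2347 RPM between the uninucleate and tricellular stages, and miR399a rose from 5.23 to 91.8 RPM.

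The first comparison, bicellular pollen against the uninucleate microspore, spans the first pollen mitosis. miR156a-f-5p rose 3.28-fold (95% interval 2.93 to 3.69), from 418 to 990 counts, and miR164a/b-5p, which targets NAC transcription factors, rose 3.14-fold (2.12 to 4.73). miR172c/d-3p, which targets APETALA2-like transcription factors, fell 6.63-fold (5.68 to 7.79), from 476 to 71.8 RPM, and miR396a-5p fell 5.04-fold (4.49 to 5.68), from 661 to 131 RPM. miR173-5p, the trigger of trans-acting siRNAs from TAS1 and TAS2, fell 2.94-fold, from 376 to 128 RPM. Small nucleolar and small nuclear RNA fragments rose from 2.53% to 4.14% of counts, and MIRNA gene tags fell from 5.38% to 3.14%. The small nucleolar RNA genes did not all rise. As examples named after their values were seen, AT3G07725 went from 554 to 10302 counts and AT2G05765 from 2852 to 1400. The library totals were 3439985 and 2480584.

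Of the 40 mature miRNAs with at least 20 counts over both libraries, 0 were at least 4-fold higher in bicellular pollen and 7 were at least 4-fold lower. These 7 were miR773a (16.9-fold, 4.44 to 144, on 2 against 47 counts), miR172c/d-3p, miR172a/b-3p, miR839-5p (5.36-fold, 2.42 to 14.0), miR394a/b-5p, miR396a-5p and miR396b-5p (4.79-fold, 3.13 to 7.61, but log2 -1.33 with tags within 2 nt of both its ends). The median log2 ratio was -0.43. DESeq2 and TMM scaling over the miRNAs moved that median by 0.53 and 0.40 and gave 2 higher and 2 lower, and 2 higher and 3 lower, respectively. In the list of miRNAs that target developmental regulators, 7 of 13 measured members were lower and 2 were higher beyond the counting interval; the median log2 ratio was -0.85, at percentile 8.94 of random lists, and miR159a stood at -0.04 (-0.15 to 0.06), or at 0.48 under DESeq2 scaling. All 3 miRNAs that target the silencing machinery were lower in RPM: miR403-3p at -0.86, miR168a/b-5p, which targets AGO1, at -0.67, and miR162a/b-3p at -0.23, which turned to 0.30 under DESeq2 and 0.18 under TMM scaling. Their median of -0.67 lay at percentile 56.9. Of the young, Arabidopsis-lineage miRNAs, 7 of 18 were lower and 4 higher, among them miR859 at -1.24, miR158a-3p at -0.83 and miR824-5p, which targets AGL16, at 0.50. Their median of -0.14 lay at percentile 92.0, and was 0.39 under DESeq2 and 0.27 under TMM scaling. miR823, which targets the DNA methyltransferase gene CMT3, rose 1.97-fold (1.06 to 3.75) and miR867 rose 1.72-fold (1.14 to 2.59). No member of the nutrient and copper list passed its interval (3 measured, median -0.75, percentile 25.2); miR845b, which targets retrotransposons, stood at -0.23 (-0.81 to 0.34), and miR828, a trigger of TAS4 siRNAs, at -0.11 on 8 against 12 counts.

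Among 21-nt tags, TAS1C (chromosome 2, 16537288 to 16538277) fell from 876 to 520 RPM (log2 -0.75, -0.85 to -0.66) and TAS2 from 340 to 232 RPM (log2 -0.55, -0.70 to -0.41), whereas TAS1A went from 154 to 202 RPM (log2 0.39, 0.21 to 0.57). The higher TAS1A value rested on the single tag ATGATATTTGTAGTAATGGCG, chosen after its values were seen: without it TAS1A fell from 82.6 to 43.9 RPM (log2 -0.91, -1.24 to -0.59), and TAS1A tags of all lengths fell as well (log2 -0.35, -0.43 to -0.27). No 21-nt tag of TAS4 was counted in any library. Fragments of the tRNAs for arginine, aspartate and glycine were the 3 largest groups of nuclear tRNA tags. Arginine tRNA tags held 121153 and 122242 RPM in these libraries, aspartate tags rose from 9659 to 31765 RPM and glycine tags from 9905 to 15309 RPM. The tags started at the first base of the tRNA in 98.2% and 98.1% of nuclear tRNA counts, most of which were arginine tags. Among single isotypes of the uninucleate microspore this share ran from 1.17% for methionine to 99.7% for arginine. The ratio of 24-nt to 21-nt counts rose from 0.580 to 0.838 (log2 0.53, 0.52 to 0.54). The log2 ratio of the MIRNA gene share was -0.78 (-0.79 to -0.77); it was -0.45 with rRNA, tRNA, snRNA and snoRNA tags left out of the total, and 0.19 when distinct tags were counted in place of reads.

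The comparison of tricellular with bicellular pollen spans the division that forms the sperm cells. Tags of the mitochondrial genome rose from 2.74% (Wilson interval 2.72 to 2.76) to 40.0% (39.9 to 40.1) of counts, a 14.6-fold rise (log2 3.87, and 0.65 when distinct tags were counted in place of reads). Mitochondrial 26S rRNA alone held 18.6% of the tricellular library, 35.3-fold above bicellular pollen, mitochondrial 18S rRNA held 5.08%, and tags of mitochondrial tRNA genes held 4.81%. Fragments of small nucleolar RNAs, the guides of rRNA modification, and of small nuclear RNAs fell 13.1-fold, from 4.14% to 0.316% (log2 -3.71, or -3.01 with mitochondrial tags left out of the total and -1.62 for distinct tags). Among miRNAs, miR399a, which acts in phosphate homeostasis, rose 32.5-fold (15.5 to 81.9), from 2.82 to 91.8 RPM, and miR173-5p fell a further 9.22-fold (6.43 to 13.6).

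The fall of small nucleolar and small nuclear RNAs was shared by 276 of the 278 annotated genes with at least 20 counts, with a median log2 ratio of -3.55, and 0 were higher. U3B and U3D, copies of the U3 snoRNA of pre-rRNA processing that share most tags, went from 4472 and 4471 counts to 487 each. Nuclear rRNA fell from 25.4% to 8.18% of counts (log2 -1.63) and nuclear tRNA from 19.9% to 10.9% (log2 -0.87). Since mitochondrial tags took up so much of the tricellular library, leaving them out of the total adds 0.70 to the log2 ratio of any set of tags outside the mitochondrial genome in this comparison, and put nuclear rRNA at -0.94 and nuclear tRNA at -0.17. Plastid tags, the marker chosen for green sporophytic tissue, stood at 5.42% and 6.01% (log2 0.15, or -0.14 with fractional assignment over loci). Among the most counted mitochondrial tags, named after their values were seen, were TCCTCAGTAGCTCAGTGGTAGAG, at the tRNA gene trnN (43544 to 43566 of the mitochondrial genome), with 184 counts in bicellular and 28091 in tricellular pollen, and TATTATTGTAACATCTGCTGATG, inside cox2, the gene of a cytochrome c oxidase subunit (6794 to 6816), with 42 and 15293. Tags of annotated pseudogenes, a class in which this annotation also places remnants of transposons, rose from 1.81% to 4.61% (log2 1.35, 1.33 to 1.36), and to 2.48% of counts from 1.39% when tags that also match an organelle genome were left out (log2 0.84); among single-locus tags little of the rise was left (log2 0.17).

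**Figure D2:**
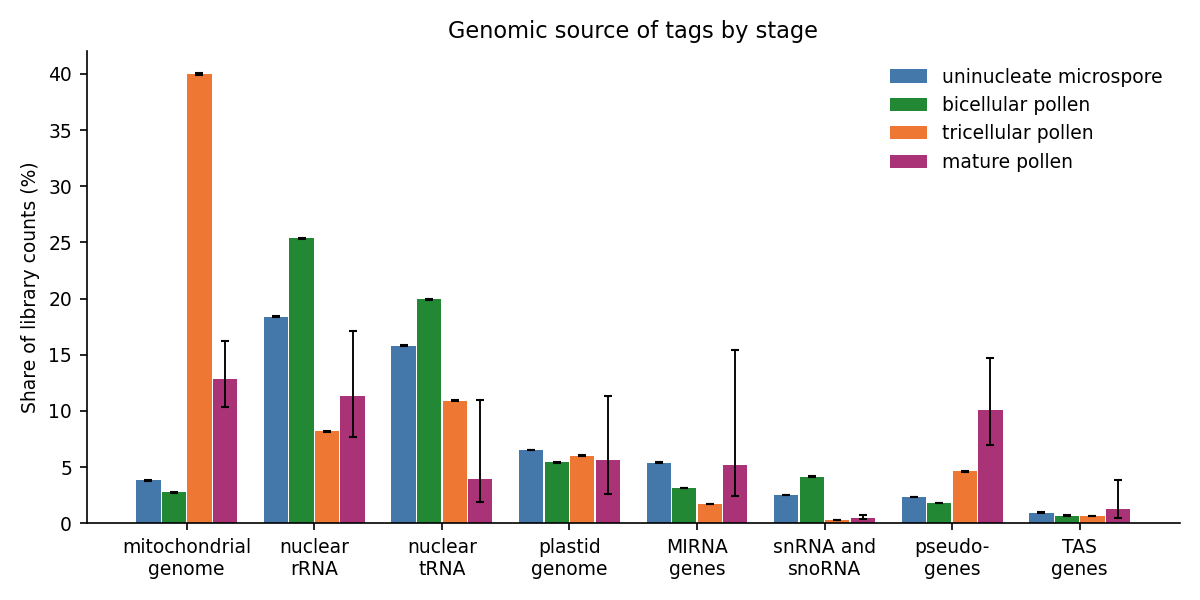
Share of each library's counts in tags from 8 genomic sources, in percent; bars are the 4 libraries, with Wilson 95% intervals for the complete libraries and the range from listing a part of the tags for mature pollen. Mitochondrial tags made up 40.0% of the tricellular library against 2.74% of the bicellular library, and pseudogene tags reached 10.0% in mature pollen.

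Of 33 mature miRNAs with at least 20 counts over both libraries, 4 were at least 4-fold higher in tricellular pollen and 6 at least 4-fold lower, with a median log2 ratio of -0.97. With mitochondrial tags left out of the total, an alternative chosen after the values were seen, the split was 6 higher and 3 lower; DESeq2 and TMM scaling each gave 6 and 3 and moved the median by 0.62 and 0.85. The 4 higher were miR399a, miR843 (8.45-fold, 4.50 to 17.5), miR157a-c-5p, which like miR156 targets SPL genes (6.57-fold, 2.93 to 17.3), and miR160a-c-5p, which targets auxin response factors (6.79-fold), the last named after its values were seen. Tags within 2 nt of both ends gave log2 1.27 for miR157a-c-5p, below 4-fold, and 5.12-fold for miR160a-c-5p. The 6 lower were miR173-5p, miR164a/b-5p (9.15-fold, 4.60 to 20.7), miR867 (7.80-fold, 3.55 to 20.3), miR845b (5.88-fold, 2.62 to 15.5), miR159a (4.94-fold, 4.31 to 5.68) and miR158b (4.12-fold, but log2 -1.30 with tags within 2 nt of both its ends). miR447a/b-3p rose 3.13-fold (1.81 to 5.68) and miR399f 1.94-fold (1.56 to 2.42). In the developmental list 3 of 11 were higher and 5 lower beyond the interval; its median of -0.57 (percentile 61.4) turned to 0.047 under DESeq2, 0.28 under TMM scaling and 0.12 without mitochondrial tags. miR156a-f-5p, at -1.26, and miR157a-c-5p, at 2.72, moved apart although they share target genes. In the silencing list miR403-3p rose (log2 0.86) while miR162a/b-3p (-1.97) and miR168a/b-5p (-1.50) fell; the median was -1.50, at percentile 28.2. Of the young miRNAs 7 of 15 were lower and 4 higher, with a median at percentile 52.6.

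At the TAS genes, TAS1A 21-nt tags rose from 202 to 413 RPM (log2 1.03, 0.87 to 1.19), or from 43.9 to 62.3 RPM without its tag ATGATATTTGTAGTAATGGCG (log2 0.50, 0.14 to 0.87; all lengths 0.31), TAS1C stood at 520 and 552 RPM (log2 0.09, -0.03 to 0.20) and TAS2 at 232 and 231 RPM (log2 -0.00, -0.18 to 0.17). With mitochondrial tags left out of the total TAS1C stood at 0.78 and TAS2 at 0.69, and TAS2 tags of all lengths stood at -0.45. Arginine tRNA tags fell from 122242 to 36069 RPM, aspartate tags from 31765 to 16050 RPM and glycine tags from 15309 to 7586 RPM. Yet 13 of the 20 isotypes measured were higher and 6 lower beyond their intervals (median log2 0.80). Among the higher ones, named after their values were seen, were leucine at 2.05 and cysteine at 0.71. The share of nuclear tRNA counts that started at the first base fell to 82.6%. Within isotypes it fell from 99.5% to 96.1% for arginine and, as an example named after its values were seen, from 96.2% to 40.3% for alanine. It rose for lysine and glutamine only. The 24-nt to 21-nt ratio of all tags was 0.838 and 0.782 (log2 -0.10, -0.11 to -0.09), and its change turned to 0.027 with tags of a count of 1 left out. Since no deposited tag ends in A, lengths were also read among nuclear tags whose next genomic base is not A, outside structural RNA, MIRNA and TAS genes. This alternative was chosen after the data were seen. There the ratio fell from 2.60 to 1.14 (log2 -1.19, -1.23 to -1.16). Organelle-matching and unmatched tags are left out as well, so the difference from all tags is not due to the next base alone. With any next base, nuclear tags outside those genes held 67048 counts of 24 nt in bicellular and 34900 in tricellular pollen. Of 21 nt they held 76811 and 55874. The log2 ratio of the MIRNA gene share was -0.90 (-0.92 to -0.88) and came to -0.20 with mitochondrial tags left out of the total.

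Mature against tricellular pollen compares pollen isolated from flowering plants with spores enriched on percoll gradients. Stage and isolation therefore differ together in this comparison. Tags of annotated pseudogenes rose from 4.61% to 10.0% of counts (log2 1.13, range 0.60 to 1.68, but 0.44 with rRNA, tRNA, snRNA and snoRNA tags left out of the total and 0.32 for distinct tags), and without tags that also match an organelle genome from 2.48% to 6.22% (log2 1.33, 1.08 to 1.64). Mitochondrial tags fell from 40.0% to 12.9% (log2 -1.64, -1.95 to -1.30), and mitochondrial rRNA from 24.5% to 2.41%. In mature pollen 12907 of the 55126 mitochondrial counts lay in a single tag inside cox2. The range is drawn from tricellular pollen and does not cover this concentration. Without the 10 most counted tags of tricellular pollen the mitochondrial shares were 33.4% and 9.83%. MIRNA gene tags rose from 1.68% to 5.22% (log2 1.63, 0.50 to 3.20). The log2 ratio was 0.95 with rRNA, tRNA, snRNA and snoRNA tags left out of the total and 1.10 with mitochondrial tags left out, and the share of distinct tags did not rise (log2 -0.27). Exact sequences of the 88 mature miRNAs looked for held 0.635% of tricellular counts and 0.160% of the listed mature pollen counts, where 9 were listed. miR158a-3p and miR859, which held 58.1% of the exact mature miRNA counts of tricellular pollen, were not among the listed tags. These shares therefore depend on which tags were listed and do not tell whether the exact sequences rose or fell. miR399a, listed with 387 counts, was estimated at 148 RPM (125 to 183) against 91.8 RPM in tricellular pollen (log2 0.69, 0.20 to 1.24). With mitochondrial tags left out of the total, which adds -0.54 here, it was not told apart (log2 0.15, -0.33 to 0.71).

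In the nuclear tags with no A as next base, the 22-nt share rose from 21.7% to 29.8% (log2 0.46, 0.34 to 0.64) and the 24-nt share fell from 16.3% to 8.35% (log2 -0.96, -1.14 to -0.73), so that the 24-nt to 21-nt ratio went from 1.14 to 0.520 (log2 -1.13, -1.34 to -0.91). In all tags this ratio was 0.782 and 0.700, a change within the range from listing a part of the tags (log2 -0.16, -0.67 to 0.38). Small nucleolar and small nuclear RNA tags stood at 0.316% and 0.478% (log2 0.59, 0.12 to 1.16); the log2 ratio was 0.056 with mitochondrial tags left out of the total and -0.065 for distinct tags. TAS genes (log2 0.99, -0.42 to 2.61), plastid tags (log2 -0.11) and nuclear tRNA (log2 -1.47, -2.56 to 0.01) were not told apart between these libraries in shares of the full total; without mitochondrial tags in the total, nuclear tRNA stood at -2.01. Apart from miR399a, miR158b was the only mature miRNA with at least 50 counts over the 4 libraries that was listed in mature pollen, and its estimated 107 RPM was not told apart from 131 RPM in tricellular pollen (log2 -0.29, -0.77 to 0.26). It was lower with mitochondrial tags left out of the total (log2 -0.83, -1.31 to -0.28).

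**Figure D3:**
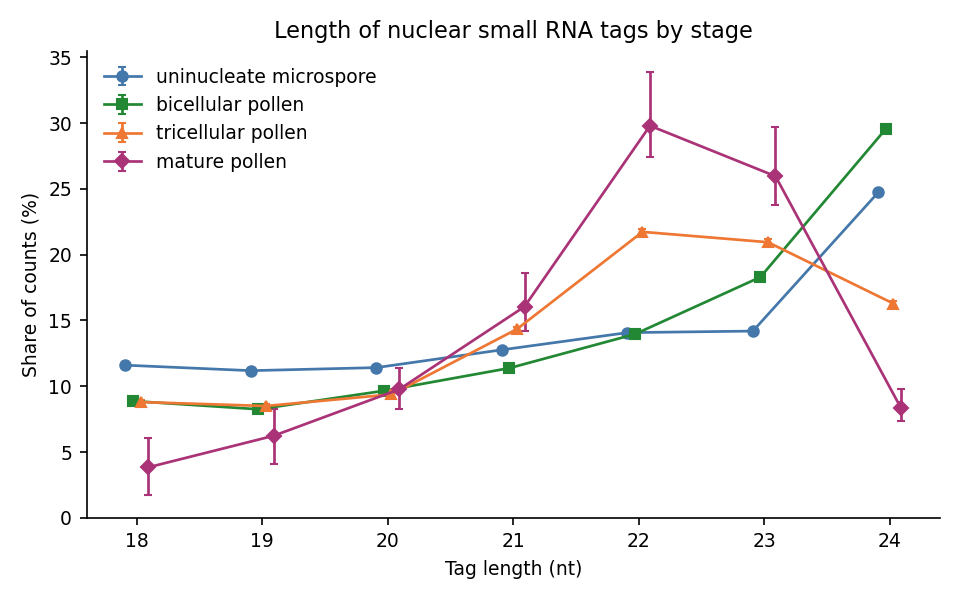
Length of nuclear tags outside structural RNA, MIRNA and TAS genes whose next genomic base is not A: the x axis is length in nt, the y axis the share of these counts in percent, lines are the 4 libraries, and error bars are Wilson 95% intervals, or for mature pollen the range from listing a part of the tags. The 24-nt share was 24.7%, 29.6%, 16.3% and 8.35% in stage order, and the 22-nt share was 14.1%, 14.0%, 21.7% and 29.8%.

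Mature pollen against the uninucleate microspore spans the whole series, and these libraries differ in isolation as well as in stage. Pseudogene tags rose from 2.35% to 10.0% of counts (log2 2.09, 1.04 to 2.85, and 1.12 for single-locus tags) and mitochondrial tags from 3.81% to 12.9% (log2 1.76, 1.19 to 2.41, and -1.87 for distinct tags), while small nucleolar and small nuclear RNA tags fell from 2.53% to 0.478% (log2 -2.41, -3.03 to -1.62, and -1.21 for distinct tags). The mitochondrial range is drawn from the uninucleate microspore. It does not cover the concentration of 12907 of the 55126 mature pollen counts in a single cox2 tag. miR399a rose from 5.23 to an estimated 148 RPM (log2 4.82, 3.90 to 5.90), and miR158b fell from 731 to an estimated 107 RPM (log2 -2.78, -3.20 to -2.29). The intervals of these 2 miRNAs rest on the total range from parts of tricellular pollen, which is narrower than that from the uninucleate microspore. Among nuclear tags with no A as next base, the 24-nt to 21-nt ratio fell from 1.94 to 0.520 (log2 -1.90, -2.08 to -1.60). In all tags the ratio was 0.580 and 0.700, not told apart (log2 0.27, -0.39 to 1.11; -0.99 for distinct tags). Tags of 22 nt from nuclear loci outside structural RNA, MIRNA and TAS genes started with G in 6.82% of counts in the uninucleate microspore, 10.2% in bicellular, 20.5% in tricellular and 26.2% in mature pollen, while 24-nt tags started with A in 48.9%, 51.5%, 51.2% and 47.4%.

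Because a single miRNA can be missing from the listed part of mature pollen, tricellular pollen was compared with the uninucleate microspore for miRNAs, a comparison added after the files were seen. miR773a fell 32.4-fold (5.55 to 1308, on 1 against 47 counts), miR173-5p 27.1-fold (19.2 to 39.5), miR172c/d-3p 19.8-fold (15.2 to 26.3) and miR396a-5p 9.87-fold (8.40 to 11.7). miR399a rose 17.5-fold (10.8 to 30.2), miR157a-c-5p 15.9-fold (44 against 4 counts) and miR843 4.16-fold (2.74 to 6.48). Of 37 mature miRNAs measured, 4 were at least 4-fold higher and 17 at least 4-fold lower, with a median log2 ratio of -1.34; DESeq2 scaling gave 7 and 6, TMM 7 and 5, and a total without mitochondrial tags 6 and 10. The fourth higher one was miR160a-c-5p (18.8-fold on 39 against 3 counts), named after its values were seen. With tags within 2 nt of both ends it was 5.07-fold higher (2.75 to 9.94), and miR157a-c-5p stood at log2 1.78, below 4-fold. Others among the lowest were miR839-5p (3 against 52 counts), miR165a/b-3p, which targets class III homeodomain transcription factors (8.97-fold), miR775 (8.26-fold), miR845b (6.90-fold), miR396b-5p (6.74-fold) and miR158b (5.60-fold); miR161.2 (2.41-fold) and miR164a/b-5p (2.91-fold) were also lower. In the silencing list miR403-3p stood at 0.00 (-0.07 to 0.07; -0.55 with tags within 2 nt of both ends) while miR162a/b-3p (-2.20) and miR168a/b-5p (-2.17) fell, with a median of -2.17 at percentile 53.9. In the developmental list 7 of 14 were lower and 4 higher (median -1.44, percentile 51.4), among the latter miR167a/b-5p, which targets auxin response factors (1.33-fold, 1.08 to 1.64), and miR156a-f-5p (1.37-fold, 1.19 to 1.58, but log2 -0.24 with tags within 2 nt of both its ends). Of the young miRNAs 8 of 16 were lower and 4 higher, such as miR447a/b-3p (3.01-fold) and miR161.1 (1.43-fold); their median of -1.10 (percentile 79.5) was 0.048 under DESeq2 and 0.16 under TMM scaling. miR399f rose 2.43-fold, so that both measured members of the nutrient list were higher.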

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

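In this part, the tests of the 10 most counted tags, of plastid tags, of the removal of terminal A, of the separate isolation of mature pollen, of mitochondrial tags as the whole cause of fewer miRNA counts, of pooled miRNA counts and of the listed part of the mature library were chosen only after the result was seen.

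Tags that end in CC directly after the last base of a tRNA gene match no place in the genome, since the CCA end of a tRNA is added after transcription, so they entered the library totals and the length ratios of all tags, but no RNA class or gene in the report. They are named here because their counts lie far above what a count of 0 allows. They held 0.309% of counts in the uninucleate microspore, 0.150% in bicellular pollen, 3.17% in tricellular pollen and 0.580% in the listed part of mature pollen. Those that fit an organelle tRNA gene, of which 4 of the 5 most counted fit a nuclear one as well, accounted for 0.225%, 0.0991%, 3.09% and 0.517%. TTCAAATCCAATAGTAGGTACC, which fits methionine tRNA genes of all 3 genomes, went from 70 counts in bicellular to 15371 in tricellular pollen, and TTCAAGTCCTGCTATACCCACC, at a mitochondrial lysine tRNA gene alone, from 33 to 4969.

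Untemplated U at the end of mature miRNAs, here U in tags without an exact match to TAIR10.1, was counted in no miRNA level of the report. Its counts were also far above what a count of 0 allows. Whether Ler-0 differs from that reference at these bases was not checked, so a genomic U in Ler-0 is not excluded. Untemplated U made up 11.4% of the mature miRNA counts, tailed tags included, in the uninucleate microspore, 16.8% in bicellular pollen and 11.4% in tricellular pollen. miR161.2 carried it in 48.4%, 50.1% and 44.9% of its counts and miR158a-3p in 14.7%, 20.7% and 17.7%, against 0.0549% and 0.157% for miR159a in the first 2 stages. For miR156a-f-5p the share fell at each stage, from 39.2% to 33.2% and 15.6%. The pooled share was carried by a few miRNAs: 4 of the 14 with at least 100 counts in each of these libraries were above 10%, and the median of the 14 was 1.74%, 1.52% and 0.877%, with no bicellular peak. Single added bases were counted after the mature sequence less its terminal A bases. For a miRNA that ends in A this is a shorter end than that used above, so these values are not parts of those shares. An unmatched U followed there in 3.66%, 4.43% and 4.55% of the counts, C in 0.217%, 0.246% and 0.159%, and G in 0.0990%, 0.104% and 0.113%. An added A cannot be seen in these tags. No biological explanation was tested.

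The mitochondrial share of the tricellular library, with the CC-ended tags that fit organelle tRNA genes beside it, was weighed against technical explanations. Without its 10 most counted tags the share still rose by a log2 ratio of 3.63 from bicellular to tricellular pollen, which argues against a few tags as the whole cause. Plastid tags, among them tags that also match the mitochondrial genome, rose by 0.15. Those outside the classes ranked before plastid fell (log2 -1.33). Green tissue carried along with the spores was taken to raise plastid tags at least 2-fold, a threshold set after the data were seen, and the rise stayed below it. Tags with a mitochondrial and no nuclear locus rose by 4.29, and those with a nuclear locus as well by 3.09. This argues against the nuclear copies of that genome in TAIR10.1 as the whole cause. Copies that this reference lacks were not tested. A difference in the tricellular spores themselves may be the cause, untested with 1 library, and so may RNA breakdown in that preparation or a difference between sequencing channels, whose pairs are not given.

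The 22-nt and pseudogene pattern from the uninucleate microspore to mature pollen was weighed in the same way. The 22-nt share rose in all tags (log2 0.69, range 0.13 to 1.39) and in nuclear tags that removal of a terminal A cannot have shortened (1.08, 0.97 to 1.21), which argues against that removal as the cause, and the pseudogene share of single-locus tags rose by 1.12 (0.69 to 1.68), so tags shared between copies are not the whole cause. Among random parts of the uninucleate library the pseudogene share reached 4.88% at the upper end of the central 95%, below the 10.0% of mature pollen, which argues against the listing of a part of the tags. The 22-nt share of those nuclear tags had already risen in tricellular pollen (0.63, 0.60 to 0.65), enriched like the uninucleate microspore, which argues against the separate isolation of mature pollen as the whole cause of that rise. A change with the stage may explain the pattern, but single-locus pseudogene tags were lower in tricellular pollen than in the uninucleate microspore (-0.30, -0.33 to -0.27), so for their rise in mature pollen stage and separate isolation differ between the same libraries and cannot be told apart.

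Fewer counts of mature miRNAs in the tricellular library were weighed against dilution. A total less mitochondrial tags adds 0.70 to the log2 ratio of every miRNA alike, so that 3 in place of 6 were at least 4-fold lower follows from arithmetic and does not tell whether mitochondrial tags dilute the other counts. With that total 14 of 33 miRNAs were still lower beyond their counting intervals, where counting error alone gives 0.825, and 12 were higher (16 and 10 with the full total). A shared shift with counting error alone does not give such numbers. Variation between libraries cannot be measured with 1 library per stage, so they do not decide whether mitochondrial tags are the whole cause. The pooled counts decide nothing, since they were lower against that total (log2 -0.27, -0.30 to -0.24) but higher without miR158a-3p and miR859 (0.11, 0.060 to 0.15). How far dilution accounts for the fewer miRNA counts as a whole stays open.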

How the results depend on the processing

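In this part, the settings with nuclear tags whose next base is not A, totals without mitochondrial tags, all annotated mature sequences and TAS1A without 1 tag, and each comparison of tricellular with uninucleate, were chosen only after the data were seen. Of 844 alternative values for 132 results, 476 stayed within their interval (counts of miRNAs within 1.5 times) and 338 moved beyond it, 19 of them across 0 in results whose own interval spans 0. In 30 a result past its interval changed sign. Below, B/U, T/B, M/T, M/U and T/U stand for bicellular over uninucleate, tricellular over bicellular, mature over tricellular, mature over uninucleate and tricellular over uninucleate; values are log2 unless they are numbers of miRNAs. The cause was not tested where none is given.

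Counting distinct tags in place of reads, the 24-nt to 21-nt change was 0.25 (B/U), -0.41 (T/B), -0.84 (M/T) and -0.99 (M/U). The MIRNA share was 0.19 (B/U), -0.46 (T/B) and -0.27 (M/T), the TAS share 0.10 (B/U), and the pseudogene share 0.035 (B/U) and 0.32 (M/T). The mitochondrial share was 0.65 (T/B) and -1.87 (M/U), the plastid share -0.54 (T/B) and the snRNA and snoRNA share -0.065 (M/T). Leaving out tags with a count of 1, the 24-nt to 21-nt change was 0.57 (B/U) and 0.027 (T/B), the MIRNA share -0.64 (B/U) and -0.93 (T/B), and the mitochondrial share 4.39 (T/B).

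For the 24-nt to 21-nt change, genome-matching tags gave 0.61 (B/U) and -0.043 (T/B), tags without structural RNA 0.49 and -0.21, and nuclear tags whose next base is not A 0.42 (B/U), -1.19 (T/B), -1.13 (M/T) and -1.90 (M/U). The MIRNA share was -0.73 (B/U) and -0.98 (T/B) with up to 1 mismatch, and -0.68 and -0.86 with single-locus tags. The mitochondrial share (T/B) was 4.69 with single-locus tags and 4.16 with fractional assignment, under which the plastid share was -0.14 (T/B). TAS tags of all lengths gave -0.10 (T/B). TAS1A stood at -0.35 (B/U) with all lengths and at -0.91 (B/U) without its most counted tag of mature pollen.

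With rRNA, tRNA, snRNA and snoRNA tags out of the total, the MIRNA share was -0.45 (B/U), -0.95 (T/B) and 0.95 (M/T), the mitochondrial share 3.08 (T/B), the plastid share -1.16 (T/B) and the pseudogene share 0.44 (M/T). For B/U, 1 miRNA was at least 4-fold higher, the young list's median was 0.19, miR161.2 stood at 0.17 and miR162a/b-3p at 0.10. With mitochondrial tags out of the total, which by construction raises the other tricellular values, the MIRNA share was -0.79 (B/U), -0.20 (T/B) and 1.10 (M/T), the TAS share 0.60 (T/B) and the developmental list's median 0.12 (T/B); 3 (T/B) and 10 (T/U) miRNAs were at least 4-fold lower.

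DESeq2 scaling gave 2 higher and 2 lower miRNAs (B/U), 3 lower (T/B), and 7 higher and 6 lower (T/U); TMM gave 2 higher and 3 lower (B/U), 3 lower (T/B), and 7 higher and 5 lower (T/U). DESeq2 put the young list's median at 0.39 (B/U) and 0.048 (T/U), the developmental list's at 0.047 (T/B), and for B/U miR161.2 at 0.37, miR162a/b-3p at 0.30 and miR158b at 0.085. TMM put them at 0.27 (B/U), 0.16 (T/U) and 0.28 (T/B), with miR161.2 at 0.25 and miR162a/b-3p at 0.18.

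A minimum of 100 counts, which tests fewer miRNAs, gave 3 lower (B/U), 2 higher and 3 lower (T/B), and 2 higher and 11 lower (T/U). A 2-fold rule, which is looser, gave 3 higher and 11 lower (B/U), 14 lower (T/B) and 7 higher (T/U). Tags within 2 nt of both ends gave 1 higher (B/U) and 12 lower (T/B), and put miR156a-f-5p at -0.24 (T/U). All annotated mature sequences, more than were looked for, gave 2 higher and 13 lower (B/U), 9 and 20 (T/B), and 9 and 37 (T/U).

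No paired analysis was possible because each stage has 1 library, and all carry replicate number 1. Leaving out tags that end in A had nothing to act on, since 0 tags do, tRNA tags of 18 to 24 nt are all the tRNA tags there are, and results by transposon superfamily were not run for want of an annotation. Depth limits the miRNAs with few counts: thinned to the shallowest complete library, 33 in place of 40 were measured for B/U and 6 in place of 7 were lower.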

Other observations

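The loci and tags named in this part were chosen after their values were seen. Pseudogenes did not move together between bicellular and tricellular pollen: among 95 with at least 20 counts of single-locus 21-nt and 22-nt tags, 39 were higher and 34 lower beyond the counting interval, with a median log2 ratio of 0.65. AT2G05025 (chromosome 2, 1773259 to 1774761) rose 65.2-fold, from 14 to 874 counts, after 38 in the uninucleate microspore. AT5G42265 (chromosome 5, 16901586 to 16901845) fell 18.7-fold, from 313 to 16 counts, after 808.

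At miR172, tags within 2 nt of both ends of miR172c/d-3p numbered 25106 in the uninucleate microspore, 1850 in bicellular pollen and 1211 in tricellular pollen, where the exact sequence had 1637, 178 and 57 counts. For miR172a/b-3p they numbered 23451, 1672 and 1158 against 22, 3 and 6, so the window counts of the 2 entries are close to each other and the length variants were not assigned to either one. A single TAS1A tag, ATGATATTTGTAGTAATGGCG, held 1484 of the 1500 TAS1A 21-nt counts listed in mature pollen, after 247 counts in the uninucleate microspore and 832 in tricellular pollen. Among tRNA isotypes outside the 3 largest, lysine tags fell from 4223 to 657 RPM between the uninucleate and bicellular stages and stood at 2432 RPM in tricellular pollen. Leucine tags went from 2938 to 1982 and then to 8224 RPM.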
